A study of Mus musculus with 15 samples.

How the data were processed

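RNA of kidneys from male C57BL/6 mice was sequenced after olive oil, CCl4, EtOH, or CCl4 and EtOH. Per the labels' protocols, frozen kidneys were extracted with a spin-column kit and libraries followed a standard Illumina procedure. The deposited values are raw read counts per gene symbol, 1 column per mouse, with no normalization. GSNAP and the mm9 build are named per the submitters' processing notes, without versions or settings. The program that counted reads, the annotation and the use of strand are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. No coordinates are printed, because the reference at hand is of another build.

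The file held 14 columns for the 15 samples of the series, and 1 olive oil sample was not analysed here. That left 3 olive oil, 4 CCl4, 4 EtOH and 3 CCl4+EtOH libraries. Of 23893 rows, 27 carried a calendar date in place of a gene symbol and were left out of library sizes and tests. They held between 0.169% and 0.209% of each library's counts. Totals per library ran from 16.4 to 23.6 M counts, so 3 counts over the olive oil group correspond to 0.0516 CPM, the usual scale of counts relative to library size. Another 72 rows formed 32 sets with identical counts in every library at a total of 100 or more, and those genes share their reads. No pair of libraries from a group agreed within sampling noise, since chi-square per gene was at least 10.3. P-values measure the spread between mice as labelled.

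Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group, libraries were scaled by TMM, and the quasi-likelihood F test with robust estimation was applied in a fit of all 14 libraries in 4 groups, with Benjamini-Hochberg adjustment over the 16105 genes tested and a threshold of 0.05. All p-values printed for genes are adjusted p of that test unless another tool is named. Errors of log2 fold changes are approximate standard errors (SE), namely the size of the change divided by the square root of F. They say little for genes with few or no counts in a group. The interaction tested whether the change with CCl4+EtOH over EtOH differed from that with CCl4 over olive oil. The CCl4 schedules were compared in a fit of 5 groups over 16442 genes. Means and SD of CPM use TMM-scaled libraries. A fold against a group at 0 counts is a lower bound set against 3 counts over the group. With 1 to 3 counts the ratio is given with an exact interval at a confidence level of 0.95, which covers counting error only.

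The 37 gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. No call of camera held with an estimated correlation in any comparison, and that p is printed beside each call described. In fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, lists passed in comparisons that include the CCl4+EtOH group.

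Groups, tests, lists, the alternatives marked as planned and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries, 10 in each direction for CCl4+EtOH vs olive oil and 5 for other comparisons, without the overlap condition for the interaction. Chance alone leaves no overlap for 10% of genes in 3 against 3 libraries. The rule added up to 4 members of each list with the smallest p, and Havcr1, Lcn2, Cyp2e1, Angptl4, Hmox1, Tnf and Timp1 in every comparison. Predicted genes were counted and not named, and some genes that the rule took are not reported here. The design foresaw a split of 4 olive oil libraries, which could not be run with 3.

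Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom with quality weights, other filters on low counts, a 5-group fit, fits of only the groups compared, a block for low or high title numbers, and each library left out in turn. Fits with the adrenal marker level as a covariate, or without the EtOH libraries that held adrenal transcripts, were added after seeing the data, and in the latter the lone EtOH library is assumed to vary like the other groups. The pipeline was tested on simulated data with 200 of 16105 genes changed. For CCl4 vs olive oil it recovered 32.8% of changes of 1.5-fold, 70.1% of 2-fold and 92.4% of 4-fold, for EtOH vs olive oil 41.8%, 56.7% and 86.4%, and for CCl4+EtOH vs olive oil 28.4%, 62.7% and 92.4%. False calls were 11 of 141 for CCl4 vs olive oil, or 7.8%, above the 5% that the threshold aims at, 6 of 129 for EtOH vs olive oil, or 4.65%, and 6 of 128 for CCl4+EtOH vs olive oil, or 4.69%.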

Results

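Kidney transcripts were counted in 14 male C57BL/6 mice. The olive oil group received the vehicle by injection for 6 weeks. The CCl4 group received the solvent carbon tetrachloride, which is known to injure liver and kidney, for 6 weeks, and in 2 of its 4 mice for another 4 weeks at a reduced dose. The EtOH group received olive oil for 6 weeks and ethanol for 4 weeks, and the CCl4+EtOH group CCl4 for 6 weeks and ethanol for 4 weeks. The source descriptions of the latter name no CCl4 in the ethanol weeks, while their titles repeat CCl4 before ethanol, so a further CCl4 course alongside ethanol is left open by the labels. Totals were lowest in EtOH replicate 4, at 16.4 M counts, and highest in olive oil replicate 2, at 23.6 M.

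The first principal component, with 43.7% of the variance, separated CCl4+EtOH from the other groups. CCl4+EtOH replicates 1 and 2 lay at 90.7 and 88.2, replicate 3 at 29.1, and the other 11 libraries between -27.6 and -9.96. On the second component, with 14.2%, EtOH replicates 1 to 3 lay at -47.4, -26.5 and -39.0 and EtOH replicate 4 at 0.93. EtOH replicates 1 to 3 held transcripts of the adrenal gland. Cyp21a1, a steroid hydroxylase of the adrenal cortex, reached between 180 and 241 CPM in those 3 libraries and 0 CPM in EtOH replicate 4.

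**Figure D1:**
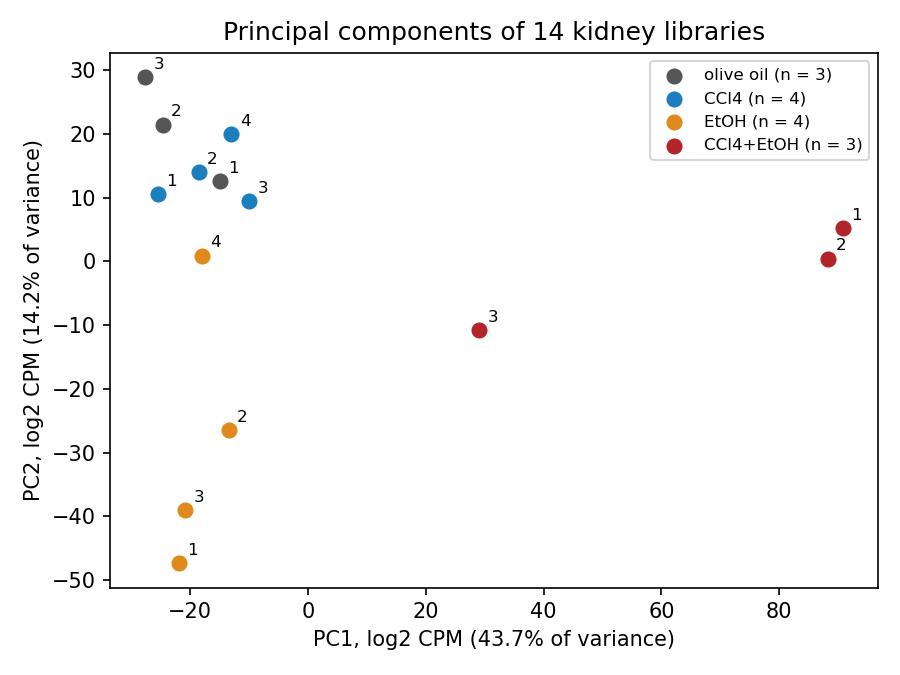
Scores of the 14 libraries on the first 2 principal components of log2 CPM, coloured by group and numbered by replicate, with the share of variance on each axis. CCl4+EtOH replicates 1 and 2 lie at 90.7 and 88.2 on the first component and replicate 3 at 29.1.

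CCl4 alone against olive oil asks what the solvent did without ethanol. No gene passed the threshold. Havcr1, a surface protein of injured proximal tubule cells, stood at 8.46 ± 5.26 CPM (SD, n = 4) after CCl4 and 7.97 ± 3.44 CPM (SD, n = 3) after olive oil. Lcn2, a secreted marker of tubule injury, stood at 6.21 ± 2.86 and 6.02 ± 3.93 CPM. Timp1, an inhibitor of matrix proteases, stood at 1.74 ± 0.96 and 3.01 ± 2.94 CPM. Cyp2e1, which metabolises both CCl4 and ethanol, stood at 1853 ± 188 and 1900 ± 685 CPM. Hmox1 was at 41.2 CPM in both groups, Angptl4 at 69.0 and 42.1 CPM, and Tnf at 0.51 and 0.40 CPM.

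Camera called 12 of 37 lists in this comparison, 8 of them higher, although no member of any list passed, adjusted over the list alone or over all genes. The fatty acid oxidation list had a median log2 change of 0.27 over 33 genes (adjusted p = 0.837 with an estimated correlation), with Slc25a20, a carnitine carrier, at 0.45 ± 0.17 (SE). The cholesterol synthesis list had a median of -0.22 over 23 genes (adjusted p = 0.837 with an estimated correlation). Immediate early genes had a median of 0.35 (adjusted p = 0.837 with an estimated correlation), with Egr1 at 1.25 ± 0.43 and Fos at 1.505 ± 0.56. Adipocyte markers had a median of 1.40 (adjusted p = 0.837 with an estimated correlation), with Fabp4 at 1.23 ± 0.61, and CCl4 replicate 3 stood apart in them. In edgeR 0 of 16105 genes were called and 640 had an unadjusted p under 0.05, with 805.25 expected by chance. DESeq2 called 1 gene and limma-voom 0.

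EtOH against olive oil compares mice given ethanol for 4 weeks after 6 weeks of olive oil with mice given the 6 weeks alone. Ethanol and the 4 further weeks cannot be told apart here, nor in CCl4+EtOH vs olive oil. In this comparison 13 genes rose and 14 fell. Gc, the vitamin D carrier protein, rose from 34.5 ± 4.80 (SD, n = 3) to 148 ± 28.6 CPM (SD, n = 4), a log2 change of 2.10 ± 0.28 (SE). Apoc3, an apolipoprotein, rose by 1.83 ± 0.28, the carbonyl reductase Cbr1 by 1.71 ± 0.30, the glutathione transferase Mgst1 by 1.64 ± 0.18 and the sugar transporter Slc5a10 by 1.53 ± 0.21. Slc22a7, an organic anion transporter, fell from 243 ± 69.0 to 40.2 ± 12.2 CPM, a log2 change of -2.60 ± 0.38. Mdk, a heparin-binding growth factor, changed by -1.99 ± 0.34, the fatty acid hydroxylase Cyp4a12a by -1.98 ± 0.33, the methyltransferase Inmt by -1.55 ± 0.23 and Itih2 by -1.51 ± 0.21.

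Of the 11 androgen-regulated genes, 1 fell, Cyp4a12a, and 9 fell adjusted over the list alone. The list's median was -1.08 (adjusted p = 0.224 with an estimated correlation). Kap, the most abundant androgen-dependent kidney transcript, stood at 10890 ± 1798 CPM (SD, n = 4) against 27610 ± 2981 (SD, n = 3), with an adjusted p of 0.0557, and Cyp7b1 at 86.4 against 294 CPM, with an adjusted p of 0.0658. In cholesterol synthesis no gene passed over all genes and 10 of 23 were lower and 1 higher adjusted over the list alone, with a median of -0.44 (adjusted p = 0.281 with an estimated correlation). Idi1 in that list was at -1.71 ± 0.32 and Cyp51 at -1.29 ± 0.30. Of 13 genes of MHC class II and antigen presentation none passed over all genes, and 6 were lower and 1 higher adjusted over the list alone, with a median of -0.29 (adjusted p = 0.421 with an estimated correlation). Cd74, the invariant chain, stood at 132 ± 22.8 against 280 ± 34.2 CPM, and H2-Eb1 at 48.4 against 103 CPM. T and NK cell markers had a median of -0.585 (adjusted p = 0.255 with an estimated correlation), with none of 13 past the threshold over all genes and 2 lower adjusted over the list alone, and macrophage markers, which camera did not call, a median of -0.233. Among 29 genes of oxidative stress, 2 rose, Cbr1 and Abcc3, and 8 were higher and 2 lower adjusted over the list alone (adjusted p = 0.421 with an estimated correlation). With the adrenal marker level as a covariate camera did not call that list (adjusted p = 0.145). It did with the title number block (adjusted p = 0.0247) and in all 14 fits with a library left out. The covariate was high in most EtOH libraries, so the lost call does not tell adrenal transcripts from the difference between the groups. Acute phase genes had a median of 0.70, with 5 of 20 higher adjusted over the list alone (adjusted p = 0.355 with an estimated correlation, and 0.0994 with the title number block), and Hp was at 2.20 ± 0.53 and Serpina3n at 1.84 ± 0.42. The podocyte gene Cdkn1c rose by 0.76 ± 0.13.

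In the same comparison all 10 adrenal markers were higher adjusted over the list alone and none over all genes, with a fitted median of 9.36, or 7.78 with 4 members at their bound (adjusted p = 0.233 with an estimated correlation). Star stood at 172 ± 114 against 5.13 ± 0.18 CPM. Chga was counted 2648 times in the EtOH libraries and 2 times in the olive oil libraries. Of the genes named in every comparison, Havcr1 stood at 4.56 ± 0.96 CPM, Lcn2 at 17.8 ± 8.02, Cyp2e1 at 1300 ± 216, Angptl4 at 57.1 ± 16.1, Hmox1 at 42.1 ± 13.9, Tnf at 0.62 ± 0.24 and Timp1 at 6.36 ± 4.12, and none passed. Camera called 19 lists, 13 of them higher.

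The 27 calls of EtOH vs olive oil depended on single libraries. Without olive oil replicates 1, 2 or 3 the counts were 15, 4 and 3, without EtOH replicates 1, 3 or 4 they were 9, 5 and 99, and without CCl4+EtOH replicate 3, which enters through the shared spread, 154. With the adrenal marker level as a covariate edgeR called 0 genes and 742 had an unadjusted p under 0.05. Without the covariate 1679 did, and DESeq2 called 350 genes and limma-voom 223. With EtOH replicate 4 as the only EtOH library 1 gene was called.

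CCl4 and EtOH together against olive oil gave the most calls in the fit of all libraries, an order that fits of only the groups compared did not keep. Of 16105 genes 3036 rose and 2670 fell, and 1308 of the former and 637 of the latter changed by over 2-fold. Havcr1 rose from 7.97 ± 3.44 to 1086 ± 948 CPM (SD, n = 3 in each group), a log2 change of 7.10 ± 0.93 (SE). Krt20, an intermediate filament protein, rose by 6.90 ± 0.87, Arhgap36 by 6.02 ± 0.89, the matrix protease Mmp7 by 6.00 ± 1.10, the interleukin Il1f6 by 6.92 ± 1.23 and Sult4a1 by 5.81 ± 0.70. Ccdc33, Atp13a4 and Vgf had no counts after olive oil and were at least 36.3-fold, 27.8-fold and 20.4-fold higher. Spaca7 was counted once in olive oil, and its ratio was 292 with a counting interval of 52.1 to 11600. Falls were led by Neurog2, with a ratio of 126 in favour of olive oil and an interval of 34.5 to 1050, and AA536875, with a ratio of 64.8 and an interval of 17.5 to 542. Col19a1 changed by -4.54 ± 0.86, Pzp by -4.44 ± 0.59, Slc22a7 by -4.21 ± 0.46, Azgp1 by -3.98 ± 0.21 and Slitrk1 by -3.89 ± 0.89.

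Of 24 tubule injury genes 22 rose, over all genes and adjusted over the list alone, with a median of 2.27 (adjusted p = 0.32 with an estimated correlation). Lcn2 rose from 6.02 ± 3.93 to 266 ± 194 CPM, the progenitor factor Sox9 by 4.62 ± 0.51 on the log2 scale, the adhesion molecule Vcam1 by 4.38 ± 0.49, and osteopontin, Spp1, from 947 ± 261.6 to 21070 ± 15200 CPM. Timp1 rose by 3.91 ± 0.92. Cell cycle genes rose in 27 of 28 cases, over all genes and adjusted over the list alone, with a median of 2.50 (adjusted p = 0.323 with an estimated correlation), Mki67 by 4.02 ± 0.72 and Cdk1 by 4.10 ± 0.69. Of 20 p53 targets 10 rose, over all genes and adjusted over the list alone, among them Eda2r at 2.68 ± 0.37 and Cdkn1a, a brake on the cell cycle, at 1.78 ± 0.33 (adjusted p = 0.32 with an estimated correlation). Immediate early genes rose in 14 of 19 cases, the same number adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), Atf3 by 3.20 ± 0.45, Egr2 by 3.71 ± 0.62 and Klf6 by 2.18 ± 0.32. CCl4+EtOH replicate 3 stood lower in these groups, with 108 CPM of Havcr1 against 2000 and 1151 CPM in replicates 1 and 2. The cell cycle list had a mean log2 CPM of 4.796 and 3.703 in replicates 1 and 2 and 2.218 in replicate 3. It stood at 1.498 to 1.749 in the olive oil libraries and at 2.465 in CCl4 replicate 4.

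Of 30 genes of NF-kB and cytokine response 25 rose, and 26 adjusted over the list alone, with a median of 1.67 (adjusted p = 0.32 with an estimated correlation). Tlr2 rose by 2.46 ± 0.39, Nfkb1 by 1.10 ± 0.15, Nfkb2 by 1.13 ± 0.17 and Tnf by 1.84 ± 0.60. All 13 genes of MHC class II and antigen presentation rose, also adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), with B2m at 1.03 ± 0.15 and the peptide transporter Tap2 at 0.79 ± 0.08. Of 27 interferon genes 18 rose, and 22 adjusted over the list alone (adjusted p = 0.544 with an estimated correlation), among them the RNA sensors Ddx58 at 1.03 ± 0.18 and Ifih1 at 0.79 ± 0.15. The mean log2 CPM of the interferon list was 4.56 and 4.685 in CCl4+EtOH replicates 1 and 2 and 3.554 in replicate 3, within the 3.463 to 3.661 of the olive oil libraries. Of 18 complement genes 14 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), C3 from 194 ± 54.3 to 2558 ± 1119 CPM, C4b by 1.66 ± 0.22 and C6 by 1.92 ± 0.28. Macrophage markers rose in 18 of 19 cases, also adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), with Mrc1 at 1.87 ± 0.30, C1qa at 1.68 ± 0.29 and C1qc at 1.89 ± 0.31. Camera did not call T and NK cell, B and plasma cell or neutrophil markers, of which 2 of 13, 0 of 8 and 1 of 10 rose, and 1, 0 and 1 adjusted over the list alone. Acute phase genes rose in 10 of 20 cases and fell in 1, by either adjustment (adjusted p = 0.32 with an estimated correlation), Serpina10 by 5.44 ± 0.79 and ceruloplasmin, Cp, by 2.75 ± 0.39. Of 30 genes of extracellular matrix and fibrosis 23 rose, and 24 adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), the membrane protease Mmp14 by 1.77 ± 0.23 and Sparc by 1.26 ± 0.20.

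All 36 genes of mitochondrial oxidative phosphorylation fell, also adjusted over the list alone, with a median of -0.56 (adjusted p = 0.32 with an estimated correlation), Ndufv1 from 378 ± 11.2 to 223 ± 39.3 CPM and Ndufa4 from 437 ± 20.8 to 273.9 ± 29.7 CPM. All 11 androgen-regulated genes fell, also adjusted over the list alone, with a median of -2.19 (adjusted p = 0.32 with an estimated correlation). Kap stood at 3370 ± 1454 CPM after CCl4+EtOH, a log2 change of -3.03 ± 0.31, Cyp4a12a changed by -4.52 ± 0.41, Cyp7b1 by -4.10 ± 0.44, Slco1a1 by -4.03 ± 0.86 and Cyp2e1 by -2.19 ± 0.27. In ethanol and aldehyde metabolism 8 of 14 genes fell and 2 rose, with 10 lower adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), Aldh3a2 at -0.97 ± 0.12, Acss2 at -1.27 ± 0.21 and Aldh1b1 at 1.54 ± 0.22. Of 33 genes of fatty acid oxidation 14 fell and 1 rose, by either adjustment (adjusted p = 0.589 with an estimated correlation), with Acadm at -1.52 ± 0.20 and Ehhadh at -1.76 ± 0.32. The mean log2 CPM of that list was 6.561 and 6.527 in CCl4+EtOH replicates 1 and 2 and 7.37 in replicate 3, above the 6.799 to 7.277 of the olive oil libraries. Cholesterol synthesis genes fell in 12 of 23 cases, and in 13 adjusted over the list alone (adjusted p = 0.323 with an estimated correlation), Cyp51 by -2.15 ± 0.34, Idi1 by -2.21 ± 0.36 and Ebp by -0.95 ± 0.14. Of 30 proximal tubule markers 14 fell, and 15 adjusted over the list alone, while the sulfate carrier Slc13a1 rose (adjusted p = 0.379 with an estimated correlation). Slc22a2 changed by -1.51 ± 0.23, Slc27a2 by -1.11 ± 0.18 and the water channel Aqp1 by -0.98 ± 0.17. The mean log2 CPM of the proximal tubule list was 8.192 and 8.092 in CCl4+EtOH replicates 1 and 2 and 9.12 in replicate 3, within the 9.068 to 9.245 of the olive oil libraries. Of 19 markers of the loop of Henle and distal tubule 9 fell and 1 rose, by either adjustment (adjusted p = 0.323 with an estimated correlation), with Wnk4 at -0.82 ± 0.16 and Bsnd at -0.70 ± 0.16. Hmox1, at 44.3 ± 11.6 CPM, and Angptl4, at 53.1 ± 18.2 CPM, did not pass.

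Camera called 21 lists in CCl4+EtOH vs olive oil, 13 of them higher. The olive oil libraries all had low title numbers and the CCl4+EtOH libraries high ones, and with that split as a block 3099 genes were called. Only the CCl4 and EtOH libraries, which held both kinds of number, informed the block. In CCl4 it followed the schedule, and in EtOH only replicate 1 had a low number.

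**Figure D2:**
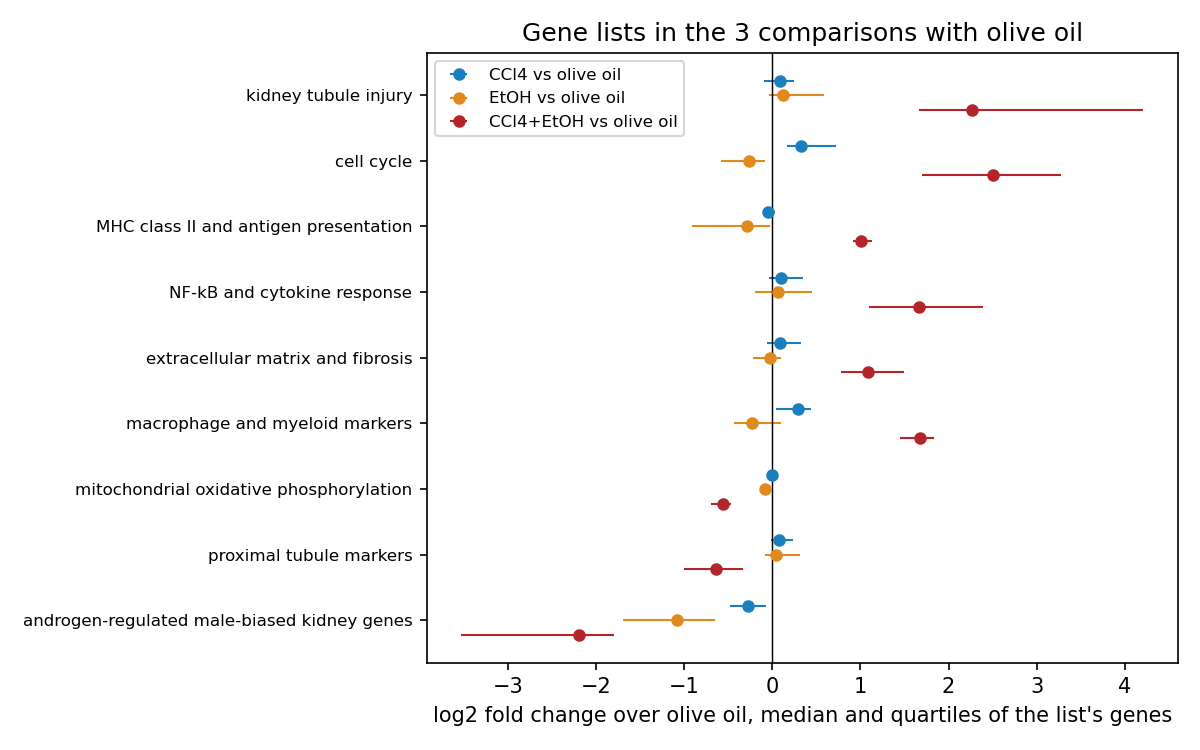
Median log2 fold change over olive oil of 9 gene lists, with bars for the quartiles of the list's genes, for CCl4, EtOH and CCl4+EtOH. The tubule injury list had a median of 0.08 after CCl4, 0.13 after EtOH and 2.27 after CCl4+EtOH, and the androgen-regulated list medians of -0.28, -1.08 and -2.19.

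CCl4+EtOH against EtOH shows the change with CCl4 in mice that received ethanol. Here 2913 genes rose and 2601 fell. Havcr1 rose from 4.56 ± 0.96 (SD, n = 4) to 1086 ± 948 CPM (SD, n = 3), a log2 change of 7.90 ± 0.85 (SE), Lcn2 by 3.92 ± 0.65, Timp1 by 2.80 ± 0.77 and Sox9 by 4.23 ± 0.44. Mmp7 and Ccdc33 had no counts after EtOH and were at least 152-fold and 47.8-fold higher, and Il1f6 had a ratio of 1230 with a counting interval of 220 to 48500. The 13 genes of MHC class II and antigen presentation all rose, also adjusted over the list alone, with a median of 1.42 (adjusted p = 0.217 with an estimated correlation), Cd74 by 2.15 ± 0.21, H2-Eb1 by 2.10 ± 0.21 and H2-Ab1 by 1.85 ± 0.19. The T cell chemokine Ccl5 rose by 2.42 ± 0.35 and Mki67 by 4.55 ± 0.67. Fatty acid oxidation genes fell in 22 of 33 cases, and in 27 adjusted over the list alone (adjusted p = 0.256 with an estimated correlation), with Acadm at -1.17 ± 0.19 and Ehhadh at -1.79 ± 0.31. Cyp2e1 changed by -1.64 ± 0.25, Gsta3 by -1.24 ± 0.18 and Dnase1 by -3.60 ± 0.38.

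The genes that fell most in CCl4+EtOH vs EtOH included adrenal markers, whose transcripts were high in EtOH replicates 1 to 3: Cyp11b1, with a ratio of 9020 and a counting interval of 1620 to 356000, Hsd3b1 at -8.45 ± 1.41 and Star at -5.07 ± 0.90. Dlk1, which is not on the adrenal list, was at -4.70 ± 0.86, and whether its transcripts came with the adrenal ones was not tested. All 10 adrenal markers fell, also adjusted over the list alone, with a fitted median of -9.81, or -8.38 with 3 members at their bound (adjusted p = 0.338 with an estimated correlation). Angptl4, Hmox1 and Tnf did not pass, at log2 changes of -0.10 ± 0.36, 0.08 ± 0.26 and 1.19 ± 0.52. Camera called 22 lists, 12 of them higher. Without CCl4+EtOH replicates 1 or 2, 3258 and 3195 genes were called, with the adrenal marker level as a covariate 1381, and with EtOH replicate 4 as the only EtOH library 335.

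CCl4+EtOH against CCl4 compares mice given ethanol after CCl4 with mice given CCl4 alone. Of the 4 CCl4 mice 2 did not have the 4 further weeks and 2 had them with the reduced CCl4 dose, so ethanol is partly confounded with time. If the CCl4+EtOH mice had no CCl4 in those weeks, it is also confounded with CCl4 dosing. Here 3007 genes rose and 2603 fell. Havcr1 rose by 7.02 ± 0.81 (SE) on the log2 scale, Krt20 by 6.20 ± 0.72, Rbmy by 6.24 ± 1.03, Il1f6 by 7.71 ± 1.17, Lcn2 by 5.44 ± 0.71, Timp1 by 4.69 ± 0.87 and Tnf by 1.49 ± 0.53. Vgf had no counts after CCl4 and was at least 25.6-fold higher. Of 24 tubule injury genes 22 rose, also adjusted over the list alone, with a median of 2.46 (adjusted p = 0.29 with an estimated correlation), Sox9 by 4.45 ± 0.45 and Cp by 3.06 ± 0.35. Complement C3 rose by 3.06 ± 0.37. In the endoplasmic reticulum stress list 12 of 25 genes rose and 2 fell, and 14 rose adjusted over the list alone (adjusted p = 0.29 with an estimated correlation), the folding factors Manf by 0.90 ± 0.22 and Pdia6 by 0.68 ± 0.16. Of 11 androgen-regulated genes 10 fell, and 11 adjusted over the list alone, with a median of -2.15 (adjusted p = 0.29 with an estimated correlation), Kap from 25520 ± 5128 (SD, n = 4) to 3370 ± 1454 CPM (SD, n = 3), Cyp4a12a by -3.80 ± 0.38 and Cyp2e1 by -2.15 ± 0.26. The lipid desaturase Scd1 changed by -1.86 ± 0.42, Col19a1 by -4.72 ± 0.84, Pzp by -4.46 ± 0.58 and Dnah9 by -4.45 ± 0.73. Neurog2 had a ratio of 61.6 in favour of CCl4 with a counting interval of 16.7 to 515, and AA536875 a ratio of 57.1 with an interval of 15.5 to 477. Angptl4 and Hmox1 did not pass, at -0.38 ± 0.36 and 0.11 ± 0.26. Camera called 21 lists, 12 of them higher. Without CCl4+EtOH replicates 1 or 2, the counts for CCl4+EtOH vs CCl4 were 3480 and 3582.

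The interaction asks whether both exposures together differed from the sum of each alone on the log scale, and the mice also differed in the 4 further weeks and may have differed in CCl4 dosing. It was higher for 884 genes and lower for 584. Havcr1 had an interaction of 7.82 ± 1.07 (SE), Serpina10 of 7.12 ± 1.14, Rbmy of 6.86 ± 1.78, the ubiquitin-like protein Ubd of 6.44 ± 0.55, Sorcs1 of 5.71 ± 1.19, Spp1 of 4.30 ± 0.65, Vcam1 of 3.99 ± 0.58 and Lcn2 of 3.87 ± 0.97. Of 13 genes of MHC class II and antigen presentation 12 were higher, and 13 adjusted over the list alone (adjusted p = 0.124 with an estimated correlation), with Cd74 at 2.36 ± 0.29 and H2-Ab1 at 2.09 ± 0.26. Of 24 tubule injury genes 13 were higher, and 21 adjusted over the list alone (adjusted p = 0.285 with an estimated correlation). Cell cycle genes were higher in 13 of 28 cases, and in 25 adjusted over the list alone (adjusted p = 0.295 with an estimated correlation), with Mcm3 at 1.91 ± 0.41. Nfkb2 had an interaction of 1.60 ± 0.23. Fatty acid oxidation genes were lower in 17 of 33 cases, and in 27 adjusted over the list alone (adjusted p = 0.279 with an estimated correlation), with Vnn1 at -1.41 ± 0.26 and Eci2 at -0.77 ± 0.15. Kap stood at -1.58 ± 0.39, Cyp4b1 at -1.62 ± 0.38 and Cyp2e1 at -1.61 ± 0.34, and Timp1, Tnf, Hmox1 and Angptl4 did not pass.

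The genes with the lowest interaction were the adrenal markers Cyp21a1 at -13.94 ± 3.83, Cyp11a1 at -12.53 ± 3.34, Hsd3b1 at -8.77 ± 1.90 and Star at -5.42 ± 1.21, and Rab3c, not on the adrenal list, at -7.59 ± 2.11. Whether Rab3c transcripts came with the adrenal ones was not tested. Camera called 24 lists, 12 of them higher. The count of 1468 genes for the interaction of CCl4 and EtOH was 292 and 539 without olive oil replicates 1 and 2, 780, 811 and 843 without CCl4 replicates 1, 2 and 4, 771 and 942 without EtOH replicates 3 and 4, and 340, 304 and 4881 without CCl4+EtOH replicates 1, 2 and 3. It was 6 with the adrenal marker level as a covariate, 3 with EtOH replicate 4 as the only EtOH library and 337 with the 10-week CCl4 libraries alone.

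**Figure D3:**
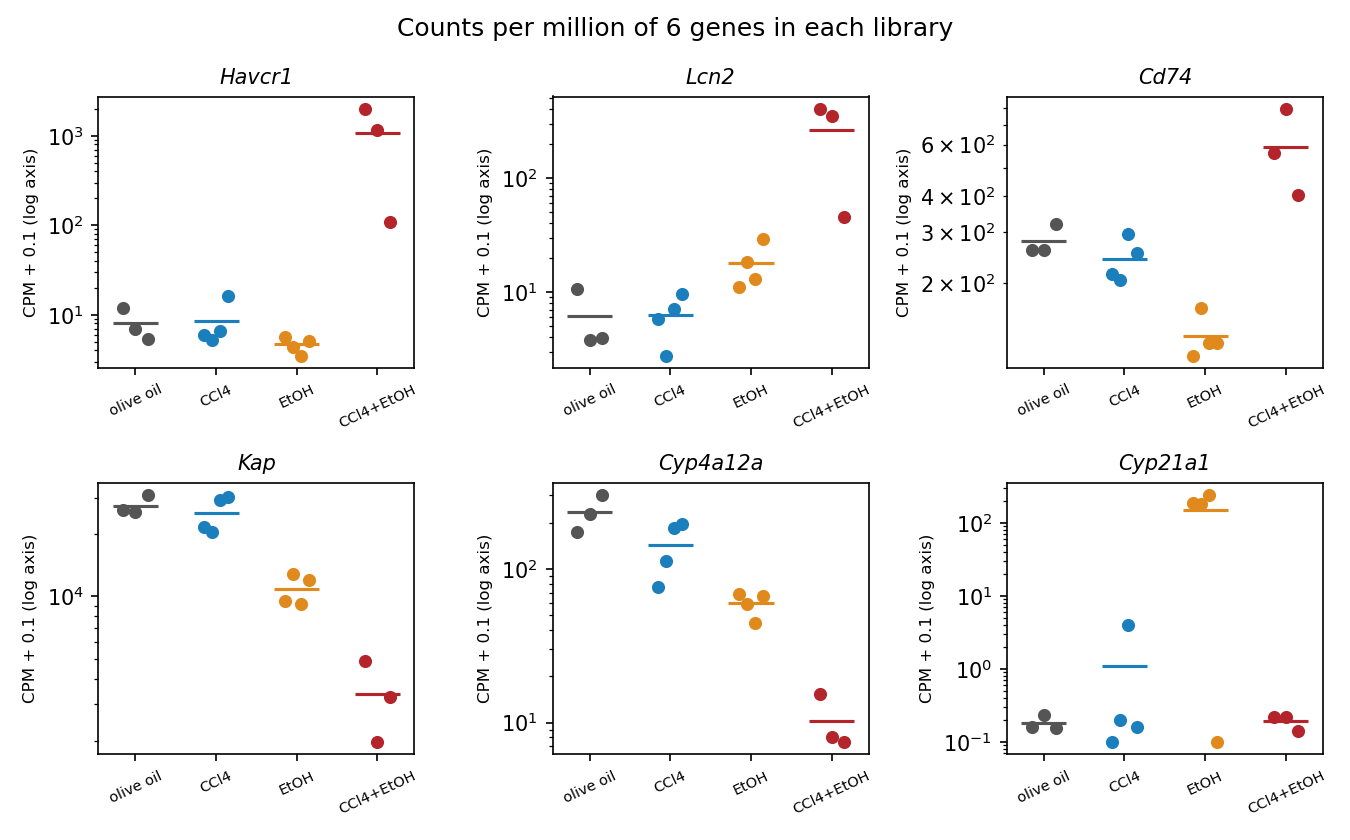
CPM of Havcr1, Lcn2, Cd74, Kap, Cyp4a12a and Cyp21a1 with 0.1 added, on log axes, with a point per library and a line at the group mean. The mean of Havcr1 was 7.97 CPM after olive oil and 1086 CPM after CCl4+EtOH, and that of Kap 27610 and 3370 CPM.

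Between the CCl4 mice of 10 weeks and of 6 weeks, 2 of each, none of 16442 genes passed the threshold in edgeR. There were 1096 at an unadjusted p under 0.05, with 822.1 expected by chance. The smallest adjusted p was 0.273, and DESeq2 called 25 genes and limma-voom 8.

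EtOH and CCl4+EtOH share their olive oil libraries. Of the 27 genes called after EtOH, 11 rose and 13 fell in CCl4+EtOH vs olive oil as well. Independent lists would share 2.45 and 2.32 genes, and simulated unchanged groups, which hold no effects to call, shared 0. Across genes the log2 changes had a correlation of 0.31, against 0.55 simulated, and a covariance of 0.15, against 0.056 simulated. Genes are not independent replicates, and part of the overlap may come from the shared olive oil libraries, of which 3 are too few to split. EtOH vs olive oil and CCl4+EtOH vs CCl4, which share no library, called 21 genes in the same direction, with 2.43 and 2.26 from independent lists, and had a covariance of 0.054 against 0.00018 simulated.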

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

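The tests of the second adrenal list and of other splits of the libraries were chosen before their results were seen. The splits that kept the EtOH and CCl4+EtOH libraries and the other tests of the patterns below were chosen only after. Of 170 values tested in the 2 groups of 4 libraries, 11 had a library far from the other 3, and chance gives about 8.5. CCl4 replicate 3 stood apart in the mean log2 CPM of adipocyte markers, at 5.851, and of adrenal markers, at -0.053, and CCl4 replicate 4 in its TMM factor, at 0.939. EtOH replicate 3 stood apart in the oxidative stress list, at 6.69, and EtOH replicate 1 in Hmox1, at 21.6 CPM against 46.0 to 52.7. EtOH replicate 4 stood apart in the renin-angiotensin-aldosterone list, at 5.968, in adrenal markers, at -1.877, in Star, at 6.47 CPM, in Chga and Cyp21a1, both at 0 CPM, and in its total of 16.4 M counts.

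The interaction term called 1468 genes and 24 lists. Leaving out single libraries gave 292 to 4881 genes, and the count fell with the adrenal marker level as a covariate. The groups also differed in weeks of treatment and may have differed in CCl4 dosing. Higher values were those of Havcr1 at 7.82, Serpina10 at 7.12, Rbmy at 6.86, Ubd at 6.44, Sorcs1 at 5.71, Spp1 at 4.30, Vcam1 at 3.99, Lcn2 at 3.87, Cd74 at 2.36, H2-Ab1 at 2.09, Mcm3 at 1.91 and Nfkb2 at 1.60. Lower values were those of Cyp21a1 at -13.94, Cyp11a1 at -12.53, Hsd3b1 at -8.77, Rab3c at -7.59, Star at -5.42, Cyp4b1 at -1.62, Cyp2e1 at -1.61, Kap at -1.58, Vnn1 at -1.41 and Eci2 at -0.77. Among these, Cyp21a1, Cyp11a1, Hsd3b1 and Star are adrenal markers, a list that was high in EtOH replicates 1 to 3. Rab3c is not on that list, and whether it followed the adrenal transcripts was not tested.

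In CCl4+EtOH replicate 3 the tubule injury list kept a median share of 0.136 of the change in replicates 1 and 2, with quartiles of 0.094 and 0.216, and the cell cycle list 0.067, while the androgen-regulated list kept 1.01, with quartiles of 0.853 and 1.06. RNA of an olive oil kidney mixed in would leave a single share in every list, and the medians differed by 0.874 with quartile ranges that did not overlap. A difference in depth is argued against by its total, which ranked 2 of the 3 in its group. RNA of EtOH replicates 1 to 3, mixed in or in its place, would bring adrenal transcripts to a median at least 6.59 higher on the log2 scale, and with EtOH replicate 4 or a CCl4 library the share of the androgen-regulated list would be lower by at least 0.333, with quartile ranges that did not overlap. A kidney not among these libraries, or a milder injury in that mouse with androgen-regulated genes fully lowered, stays open as a hypothesis, and no biological explanation was tested.

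Adrenal markers stood at 5.64, 4.96 and 5.70 in EtOH replicates 1 to 3 and between -2.11 and -1.73 in the olive oil libraries, and CCl4 replicate 3, which had no ethanol, also lay above these, at -0.053 with 3.90 CPM of Cyp21a1. Induction by ethanol in every treated kidney would raise all 7 ethanol-treated libraries above the highest olive oil library, and 3 did, which leaves induction in those 3 mice open. Adrenal tissue in those samples may be the source: 8 of 12 genes of a second list were over 2-fold higher, Cyp11b2 at 9.01, 9.60 and 11.9 CPM and 0 in every olive oil library, but the list's median log2 difference of 2.89 fell short of the bound of 3 set beforehand and lay above the bound of 1 against it. Fdx1, Ddc and Slc18a1 of that list are also expressed in olive oil kidneys, at 62.4 to 489 CPM, and were not over 2-fold higher. Penk, at only 1.83 to 2.22 CPM in olive oil kidneys, was not higher either, with a log2 difference of -0.0791. This explanation therefore stays open.

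Androgen-regulated genes had median log2 differences from the olive oil mean of -2.26, -2.59 and -2.61 in the CCl4+EtOH libraries and -1.03, -0.763, -1.58 and -0.825 in EtOH replicates 1 to 4, but also of -0.693 and -0.62 in CCl4 replicates 1 and 2, against 0.0662 and 0.146 in CCl4 replicates 3 and 4 and -0.398, -0.342 and 0.469 in olive oil. Other tissue in EtOH replicates 1 to 3 is argued against by the proximal tubule list, which dilution would lower alike and whose median lay 1.31 above the androgen-regulated list in those libraries. That list also argues against an even loss of proximal tubule transcripts in EtOH, where its median lay 1.12 above the androgen-regulated list. In CCl4+EtOH the proximal tubule list was itself lower in replicates 1 and 2, with medians of -0.891 and -1.16, and stood at -0.0533 in replicate 3. Its median there lay 1.55 above the androgen-regulated list, so an even loss does not account for the whole fall. Quartile ranges of the 2 lists did not overlap in any of these. A difference between low and high title numbers cannot be told apart from the CCl4 schedule, since the CCl4 libraries with high numbers, which lay 0.568 higher, were also those of 10 weeks. Lower androgen action may be a biological explanation, as a hypothesis, and hormone levels were not measured. The median of female-biased genes, given under the other observations, went against it by the rule set beforehand, but those genes went both ways.

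Other splits of the same libraries do not exclude chance for EtOH vs olive oil, where 2 of 35 splits called as many genes, 27 in the real split and 64 at most in another. The split with 64 genes set EtOH replicate 4 with the olive oil libraries and so followed the adrenal transcripts. For CCl4 vs olive oil all 35 splits called at least the real 0 genes and at most 4. The share was under 0.05 for CCl4+EtOH vs EtOH, where 1 of 35 splits reached the real 5514 and the highest other gave 1586. For CCl4+EtOH vs CCl4 it was also under 0.05, where 1 of 35 reached 5610 and the highest other gave 691. These shares are the smallest that 35 splits allow and were not adjusted over comparisons, so they argue against chance without excluding it. For the interaction 3 of 100 drawn splits reached 1468, with 3188 in the highest other. Among those drawn, splits whose CCl4+EtOH group was the real one gave 1423 or more and the others at most 22. That share therefore follows the difference between CCl4+EtOH and EtOH and decides nothing about the interaction. With the EtOH and CCl4+EtOH libraries kept, 29 of 35 splits reached 1468, with 3188 in the highest other, but they hold that difference fixed and exchange libraries between which 0 genes were called, so they decide nothing either. CCl4+EtOH vs olive oil has 10 splits, too few for a share under 0.05, with 1 reaching the real 5706 and 1 gene in the highest other.

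For the number of lists called by camera, chance was not excluded: 17 of 35 splits reached the real 12 for CCl4 vs olive oil, with 21 in the highest other, 2 of 35 reached 19 for EtOH vs olive oil, with 22, 12 of 35 reached 22 for CCl4+EtOH vs EtOH, with 29, 15 of 35 reached 21 for CCl4+EtOH vs CCl4, with 28, and 18 of 100 reached 24 for the interaction, with 31. With the EtOH and CCl4+EtOH libraries kept 4 of 35 splits reached 24, with 25 in the highest other, which decides nothing for the same reason. CCl4+EtOH vs olive oil has too few splits, with 4 of 10 at or above the real 21 and 24 in the highest other.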

How the results depend on the processing

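Fits with the adrenal marker level as a covariate or without the 3 EtOH libraries that held adrenal transcripts, and the comparison without shared libraries, were chosen after the data were seen. Of 5381 values of 213 gene and comparison pairs under the alternatives, 4927 kept their direction and their side of the threshold, 306 lost the call, 74 gained it and 74 turned direction. With DESeq2 size factors all 213 were kept. The pairs were picked in the main fit and the alternatives refit the same counts. Pairs uncalled in both fits also count as kept, so the tally is no independent support. No paired analysis was possible because the labels give each mouse a number of its own. Where no reason is given below, the cause was not tested. Depth limits genes near 3 counts.

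DESeq2 called 1 gene in CCl4 vs olive oil, 350 in EtOH vs olive oil, 2519 in the interaction of CCl4 and EtOH, 25 between the CCl4 schedules and 211 shared by EtOH and CCl4+EtOH vs olive oil, where the main count was 24. The corresponding limma-voom counts were 0, 223, 4810, 8 and 134. The fit of 5 groups called 62 genes for EtOH vs olive oil with 50 shared, the title number block 65 with 44 shared, and fits of only the groups compared 94 with 60 shared. CCl4+EtOH vs olive oil had 3099 genes with the title number block and 3276 with only its groups, and CCl4+EtOH vs EtOH 3390 with only its groups, where fewer libraries set the spread. The interaction had 337 genes with the 10-week CCl4 libraries only. At an adjusted p under 0.01, 1 gene was shared.

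With the adrenal covariate EtOH vs olive oil had 0 genes, CCl4+EtOH vs EtOH 1381, the interaction 6, shared calls 0 and lists in EtOH vs olive oil 12. Without the 3 libraries the counts were 1, 335, 3 and 0. Both rest on EtOH replicate 4 as the EtOH library without adrenal transcripts. Camera with an estimated correlation called 0 lists in every comparison, and fry 0 for CCl4 vs olive oil, 0 for EtOH vs olive oil and 15 for the interaction.

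Leaving out each library in turn gave 3 to 154 genes for EtOH vs olive oil, 3904 to 7417 for CCl4+EtOH vs olive oil, 3195 to 7417 for CCl4+EtOH vs EtOH, 3480 to 7396 for CCl4+EtOH vs CCl4, 292 to 4881 for the interaction, 0 to 1 between CCl4 schedules and 3 to 94 shared calls. CCl4+EtOH replicate 3 gave the highest of each. Genes that turned direction were not called in the comparison, apart from Cyp11a1 and Cyp21a1 in the interaction and Cyp11a1 and Chga in CCl4+EtOH vs EtOH. Over the libraries left out, log2 changes ran from -0.120 to 0.0957 for Hmox1 in CCl4 vs olive oil, -1.23 to 0.313 for Timp1 in CCl4 vs olive oil, -0.442 to 0.471 for Havcr1 in CCl4 vs olive oil, -0.232 to 0.708 for Lcn2 in CCl4 vs olive oil, -0.103 to 0.850 for Tnf in CCl4 vs olive oil, -0.140 to 0.274 for Hmox1 in interaction of CCl4 and EtOH, -0.221 to 0.294 for Cyp2e1 in CCl4 vs olive oil, -0.0994 to 0.246 for Hmox1 in EtOH vs olive oil, -0.0397 to 0.299 for Hmox1 in CCl4+EtOH vs olive oil, -0.416 to 0.0578 for Angptl4 in CCl4+EtOH vs EtOH, -0.142 to 0.272 for Hmox1 in CCl4+EtOH vs EtOH and -0.0408 to 0.302 for Hmox1 in CCl4+EtOH vs CCl4.

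Hmox1 in CCl4 vs olive oil turned to 0.00557 with upper-quartile factors, 0.000439 with DESeq2, 0.00144 without a filter, 0.00267 at 1 CPM, 0.000591 with only its groups, 0.158 with the 10-week libraries and 0.0153 with the adrenal covariate. Havcr1 in CCl4 vs olive oil turned to -0.0928 with limma-voom, -0.00261 with 5 groups, -0.183 with the title number block and -0.529 with the 6-week libraries. Lcn2 in CCl4 vs olive oil turned to -0.0708 with limma-voom, -0.0196 with 5 groups, -0.478 with the title number block and -0.516 with the 6-week libraries. Cyp2e1 in CCl4 vs olive oil turned to 0.130 with limma-voom and 0.0565 with the 10-week libraries. Hmox1 in EtOH vs olive oil turned to -0.00763 with limma-voom and -0.538 with the title number block. Angptl4 in CCl4+EtOH vs EtOH turned to 0.0713 with limma-voom and 0.0902 with the title number block. Timp1 in EtOH vs olive oil turned to -0.0713 with the title number block. Hmox1 in CCl4+EtOH vs olive oil turned to -0.572 with the title number block. Hmox1 in CCl4+EtOH vs EtOH turned to -0.0337 with the title number block, -0.114 with the adrenal covariate and -0.132 without the 3 libraries. Angptl4 in CCl4+EtOH vs CCl4 turned to 0.0607 with the title number block and 0.165 with the 10-week libraries. Hmox1 in CCl4+EtOH vs CCl4 turned to -0.231 with the title number block and -0.0553 with the 10-week libraries. Tnf in CCl4 vs olive oil turned to -0.042 with the 6-week libraries. Hmox1 in interaction of CCl4 and EtOH turned to -0.0833 with the 10-week libraries, -0.129 with the adrenal covariate and -0.129 without the 3 libraries. Cyp21a1 in EtOH vs olive oil turned to -2.40 with the adrenal covariate and -3.87 without the 3 libraries. Cyp11a1 in CCl4+EtOH vs EtOH turned to 1.21 with the adrenal covariate and 2.91 without the 3 libraries. Chga in CCl4+EtOH vs EtOH turned to 0.859 with the adrenal covariate. Cyp21a1 in interaction of CCl4 and EtOH turned to 1.37 with the adrenal covariate and 0.559 without the 3 libraries. Cyp11a1 in interaction of CCl4 and EtOH turned to 0.823 with the adrenal covariate and 0.9996 without the 3 libraries.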

Other observations

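The test of female-biased genes was chosen before its result was seen, except that Slc22a7 had been seen to be lower. Cell type markers varied between mice of a group. Neutrophil markers had a mean log2 CPM of 3.97 in EtOH replicate 4 and between 0.00196 and 1.67 in EtOH replicates 1 to 3. Red cell markers stood at 7.86 in CCl4+EtOH replicate 3 and at 5.32 and 4.59 in replicates 1 and 2. Adipocyte markers ran from 1.15 to 4.43 over the olive oil libraries and from 2.92 to 5.71 over the CCl4+EtOH libraries. Podocyte markers rose in 6 of 14 cases in CCl4+EtOH vs olive oil, the same number adjusted over the list alone (adjusted p = 0.529 with an estimated correlation), with the intermediate filament gene Nes at 1.37 ± 0.19 (SE), and camera did not call the list without CCl4+EtOH replicate 3. Collecting duct markers fell in 3 of 18 cases and in 0 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation), with the water channel Aqp3 at -0.76 ± 0.23 and the sodium channel subunit Scnn1a at -0.68 ± 0.21. Their mean log2 CPM was 4.794 and 5.097 in CCl4+EtOH replicates 1 and 2 and 5.585 in replicate 3, within the 5.544 to 5.709 of olive oil, and camera did not call them without CCl4+EtOH replicate 1 or with the title number block (adjusted p = 0.346). Oxidative stress genes went both ways, with 6 of 29 higher and 12 lower, or 7 and 14 adjusted over the list alone, Akr1b8 at 3.29 ± 0.45 and Me1 at -1.58 ± 0.17.

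Lower androgen action may account for the lower androgen-regulated genes, and female-biased kidney genes would then be higher. Their median log2 change in CCl4+EtOH vs olive oil was -0.358 over 4 genes. A negative median was set beforehand as the outcome against lower androgen action, so by that rule the value argues against it. The 4 genes went both ways, which that rule did not consider, so the median of so few genes is not taken to decide it. Slc7a12 rose by 1.70 ± 0.55 and Prlr by 1.81 ± 0.65, while Cyp2a4 changed by -2.41 ± 0.28 and Slc22a7 by -4.21 ± 0.46.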
